A study of Mus musculus and Homo sapiens with 33 samples.

How the data were processed

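The series holds 33 samples. The 6 RNA-seq libraries of KPL cells were used, 3 of control cells and 3 of cells treated with 4-hydroxytamoxifen (4-OHT), and the 27 ChIP-seq samples were not analysed here. Per the labels, RNA was purified with a DNase step, polyadenylated RNA was selected and libraries were made with an NEBNext Ultra kit. Groups and replicate numbers were taken from the sample labels.

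The count matrix, as deposited by the authors, holds whole-number read counts per Ensembl gene that are not normalised. The authors' comparison table holds log2 values, namely the log2 fold change of 4-OHT over control and the log2 mean CPM per gene, per the file headers. It also holds the p-value and the FDR of each gene, per the file headers, and the authors' test and scaling are not given in the sources used here. The submitters' processing notes list TopHat2 2.1.0, Bowtie 1.1.2, Bowtie2, bedtools 2.26.0, edgeR and the builds GRCm38.p6, mm10, hg19 and GRCh37, with no roles. The counting program, the annotation release and the use of strand are not given in the sources used here. Reads of overlapping genes, antisense genes and near-identical copies can therefore not be told apart with certainty.

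The matrix has 38951 lines. For 12 Ensembl IDs several identical lines were present, and the 27 repeats, with 0.109% of the reads, were kept once, which left 38924 IDs. No reads were counted for 17638 IDs, and 979 IDs had no symbol. Symbols of 31674 IDs matched the RefSeq gene table of GRCm38.p6, from which coordinates, gene types and genomic spans were taken. Library totals lay between 5859826 and 5913942 reads, a ratio of 1.0092, so precision differed little between libraries.

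Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with few reads were removed with filterByExpr (minimum count 10, minimum total 15), which took out 25569 IDs and left 13355 genes with 99.7% of the reads. TMM factors lay between 0.994 and 1.01. The groups were compared with the robust quasi-likelihood F test of edgeR, two-sided, without a replicate block, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested with a threshold of 0.05. CPM values use TMM-scaled library sizes. The common dispersion was 0.00066, a biological coefficient of variation of 2.58%. Pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 1.26 to 1.48 over genes with a summed count of at least 20, against 2.90 to 3.25 between groups), so no pair was merged as 1 library deposited more than once, which does not show that they came from separate cultures. The first principal component held 35.3% of the variance and separated the groups.

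Gene lists, cell type markers, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Each of 27 lists and marker sets was compared with the other genes by camera in limma on voom values, two-sided, with a preset correlation of 0.01, and 23 had at least 3 tested members. Of these, 13 passed an adjusted p of 0.05 (10 lower and 3 higher), and 7 passed with an estimated correlation. With the preset correlation, camera takes its degrees of freedom from the number of genes, and with an estimated one from the 6 libraries. The preset p-values therefore do not carry the full uncertainty of 6 libraries. The fry test asks whether the genes of a list move on balance 1 way and does not compare them with other genes. Mitotic and G1/S genes were compared by camera among the members of only these lists. Named genes were all tested members of the MuvB list, the 2 members with the smallest p per other list among those called (or the member with the highest mean CPM where none was called), and the 6 largest falls and 6 largest rises among called genes with groups that do not overlap and a mean CPM of at least 1 in the higher group, where genes without a symbol, predicted genes and pseudogenes were skipped. Ctgf, Cyr61, Ankrd1, Amotl2, Cdk1, Ccnb1, Plk1, Aurka, Top2a and Birc5 were named whatever their test gave. Other genes were named after their values were seen, and the text says so. Some genes are not reported here but remain in the counts.

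The procedure was tested on counts simulated for the 13355 genes. It recovered 64% of genes changed 1.25-fold, 86% at 1.5-fold, 98% at 2-fold and 100% at 3-fold (50 genes each), and 13 of 13095 unchanged genes were called, which is 5.70% of the 228 calls. The changed genes were drawn only from genes above a minimum expected count, so recovery of genes with few reads was not tested. Of 100 unchanged lists 0 had a camera p under 0.05. Genes were simulated independently of each other, so this does not show how camera behaves on lists of correlated genes.

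Alternatives were other scalings, no filter and a stricter filter (CPM of at least 1 in 3 libraries), leaving out each library, a replicate block, protein-coding genes only, DESeq2 1.42.0, limma-voom, a 1.5-fold null hypothesis (glmTreat), a correction for the trend on gene span, camera with an estimated correlation and lists without their most changed member. A genomic span was known for 97.5% of the genes tested. GC content was not corrected, since no GC values were used here.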

Results

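The RNA-seq part of the series measured polyadenylated RNA of KPL cells, a murine lung adenocarcinoma line, with and without 4-hydroxytamoxifen (4-OHT). The labels state that 4-OHT, given for 72 hours at a dose written as 10 nm, deletes Lin9, which encodes a core subunit of the MuvB complex. There were 3 control libraries, named EtOH (ethanol) in the sample descriptions, and 3 4-OHT libraries. The control libraries held 5871665, 5876193 and 5859826 counted reads, and the 4-OHT libraries held 5894309, 5913942 and 5904473. Between 18365 and 18601 genes had a read in each library, and mitochondrially encoded genes took 1.56% to 1.66% of the reads. The 6 libraries are not described as separate cultures, so the p-values measure at most the spread between these libraries, which may be technical. ChIP-seq libraries of the same series, 13 from KPL cells and 14 from human MCF10A-YAP5SA cells, were not analysed here.

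The question put to these libraries was which genes change their RNA level when Lin9 is depleted. Lin9 itself (ENSMUSG00000058729, chromosome 1, 180641150 to 180690687 in the RefSeq annotation of GRCm38.p6) was counted at 156, 124 and 159 reads in the control libraries and at 108, 107 and 101 reads in the 4-OHT libraries. Its level fell from 25.1 ± 3.29 to 17.8 ± 0.615 CPM (reads scaled to a common library size, mean ± SD, n = 3 each), a log2 fold change of -0.49 (SE 0.11, edgeR adjusted p = 0.0011). The 4-OHT libraries thus kept 71.1% of the control level in the whole-gene count. The count covers the whole gene, so reads from exons outside a deleted part stay in it. Against a null hypothesis of a 1.5-fold change the Lin9 call was lost (edgeR glmTreat adjusted p = 1).

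After 4-OHT, 70 of 104 tested genes of mitosis were lower, and the largest falls within the mitotic lists were those of Aspm, Nusap1, Cenpa, Plk1, Mki67 and Cenpf, whose levels were 0.311 to 0.406 times those of control. Of 13355 genes tested, 691 were lower and 616 were higher in the 4-OHT libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). With library totals alone as the scaling, 647 were lower and 705 higher. Most changes were small. Among the called genes 43 were lower and 21 higher by 2-fold or more, and the median size of the log2 fold change was 0.32 among those lower and 0.27 among those higher. The 3 control and 3 4-OHT CPM values did not overlap for 24.3% of the genes tested, where chance gives 10%. DESeq2 called 350 lower and 174 higher, and edgeR called all 524 of these too. Against a null hypothesis of a 1.5-fold change 45 genes were lower and 0 higher (edgeR glmTreat), with 92 lower and 44 higher at an unadjusted p under 0.05. Without control replicate 1 the number of genes called higher was 403.

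**Figure D1:**
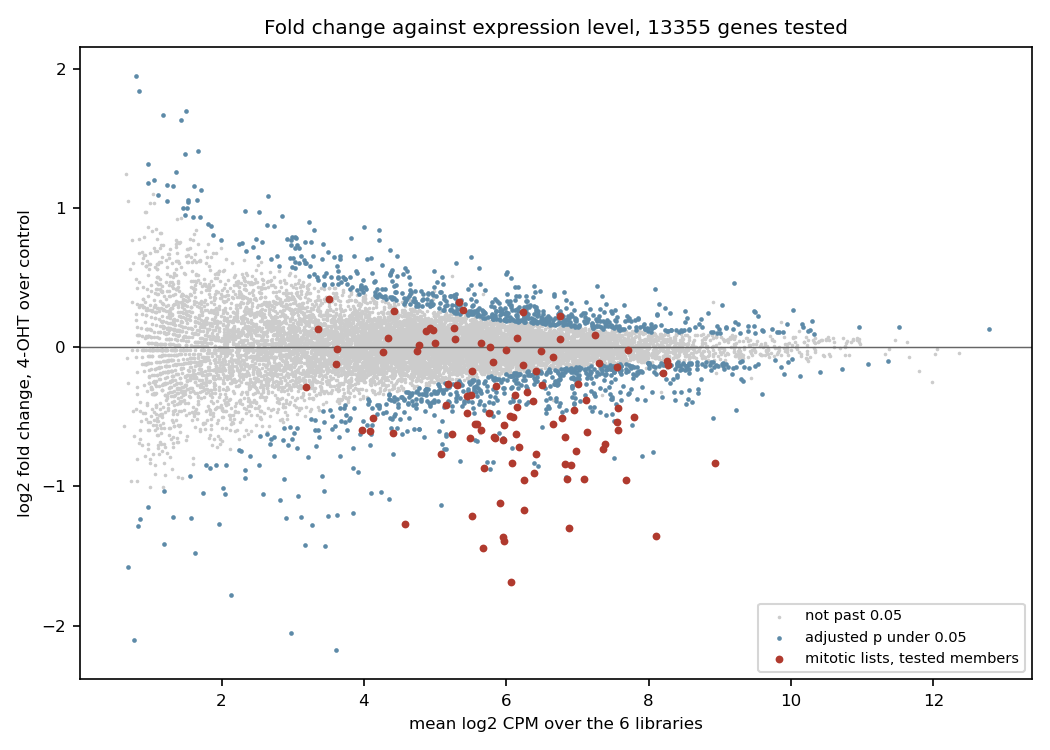
Log2 fold change (4-OHT over control, vertical axis) against the mean log2 CPM over the 6 libraries (horizontal axis) for each of the 13355 genes tested; grey points did not pass an adjusted p of 0.05, blue points did and red points are the tested members of the mitotic lists whatever their test gave. Most red points lie below 0, with a median of -0.45.

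The mitotic lists, fixed before the data were examined, held 104 tested genes when joined. Of these, 70 were lower, 4 were higher and 30 did not pass the test. Adjusted over the list alone, 74 were lower and 6 higher. Their median log2 fold change was -0.45, so that the median level fell by 26.6%, and the list was lower than the other genes tested (camera adjusted p = 5.7e-72, and adjusted p = 0.0016 with an estimated correlation). Mki67, a proliferation antigen of the chromosome surface, fell from 438.2 ± 23.2 to 171.5 ± 8.09 CPM, a log2 fold change of -1.35 (SE 0.04, edgeR adjusted p = 9.1e-45). Top2a, the topoisomerase that untangles sister chromatids, fell from 650.1 ± 22.7 to 365.3 ± 12.2 CPM (log2 fold change -0.83, SE 0.03). The 4 members that were higher were Zwilch (log2 fold change 0.33), Cenph (0.27), Plk4 (0.25) and Bub1 (0.22), named after their values were seen. None of the 4 passed in DESeq2, where their adjusted p lay between 0.059 and 0.313. The Cenph call was also lost without control replicate 1 (adjusted p = 0.201) and without 4-OHT replicate 3 (adjusted p = 0.375).

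Among the mitotic kinases, cyclins and ubiquitin ligase factors, 20 of 25 tested genes were lower and 1, Plk4, was higher, the same numbers as adjusted over the list alone (median -0.61, camera adjusted p = 5.8e-43). Plk1, a kinase that drives mitotic entry and spindle assembly, fell from 99.4 ± 5.63 to 38.6 ± 4.03 CPM (log2 fold change -1.36, SE 0.07). Plk1 has a pseudogene in the matrix, Plk-ps1, named after its value was seen, whose count fell by 1.22 on the log2 scale, and the counting could divide reads between the pair. Cdc20, an activator of the anaphase-promoting complex, changed by -1.17 (SE 0.06), the kinase gene Aurka by -1.12 (SE 0.07), the cyclin gene Ccnb1 by -0.84 (SE 0.05) and its kinase partner Cdk1 by -0.61 (SE 0.05), all on the log2 scale.

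Of 25 tested spindle and kinesin genes, 24 were lower and 0 higher, as when adjusted over the list alone (edgeR; median -0.66, camera adjusted p = 7.1e-65). Aspm, which encodes a spindle pole protein, fell from 119.0 ± 5.31 to 37.0 ± 1.68 CPM (log2 fold change -1.68, SE 0.06). Nusap1, which encodes a microtubule-binding protein of the spindle, changed by -1.44 (SE 0.07) on the same scale. All 14 cytokinesis genes were lower, also when adjusted over the list alone (median -0.50, camera adjusted p = 8.1e-35), although this list shares members with the others. Prc1, which bundles microtubules of the central spindle, changed by -0.94 (SE 0.05). Birc5, a subunit of the chromosomal passenger complex, fell less, from 99.0 ± 6.51 to 82.1 ± 1.22 CPM (log2 fold change -0.27, SE 0.06, edgeR adjusted p = 0.00031).

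Of 38 tested kinetochore and spindle checkpoint genes, 17 were lower, 3 were higher and 18 did not pass; adjusted over the list alone, 17 were lower and 5 higher (median -0.14, camera adjusted p = 9.5e-10). Cenpa, the centromeric histone H3 variant, changed by -1.39 (SE 0.07) on the log2 scale and Cenpf, a kinetochore protein gene, by -1.30 (SE 0.05). Of 13 tested chromosome condensation genes, 6 were lower and 0 higher (8 and 0 adjusted over the list alone, median -0.13, camera adjusted p = 3.8e-17). With an estimated correlation each of these mitotic lists still passed, with adjusted p between 0.0010 for spindle and kinesins and 0.033 for kinetochore and checkpoint.

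**Figure D2:**
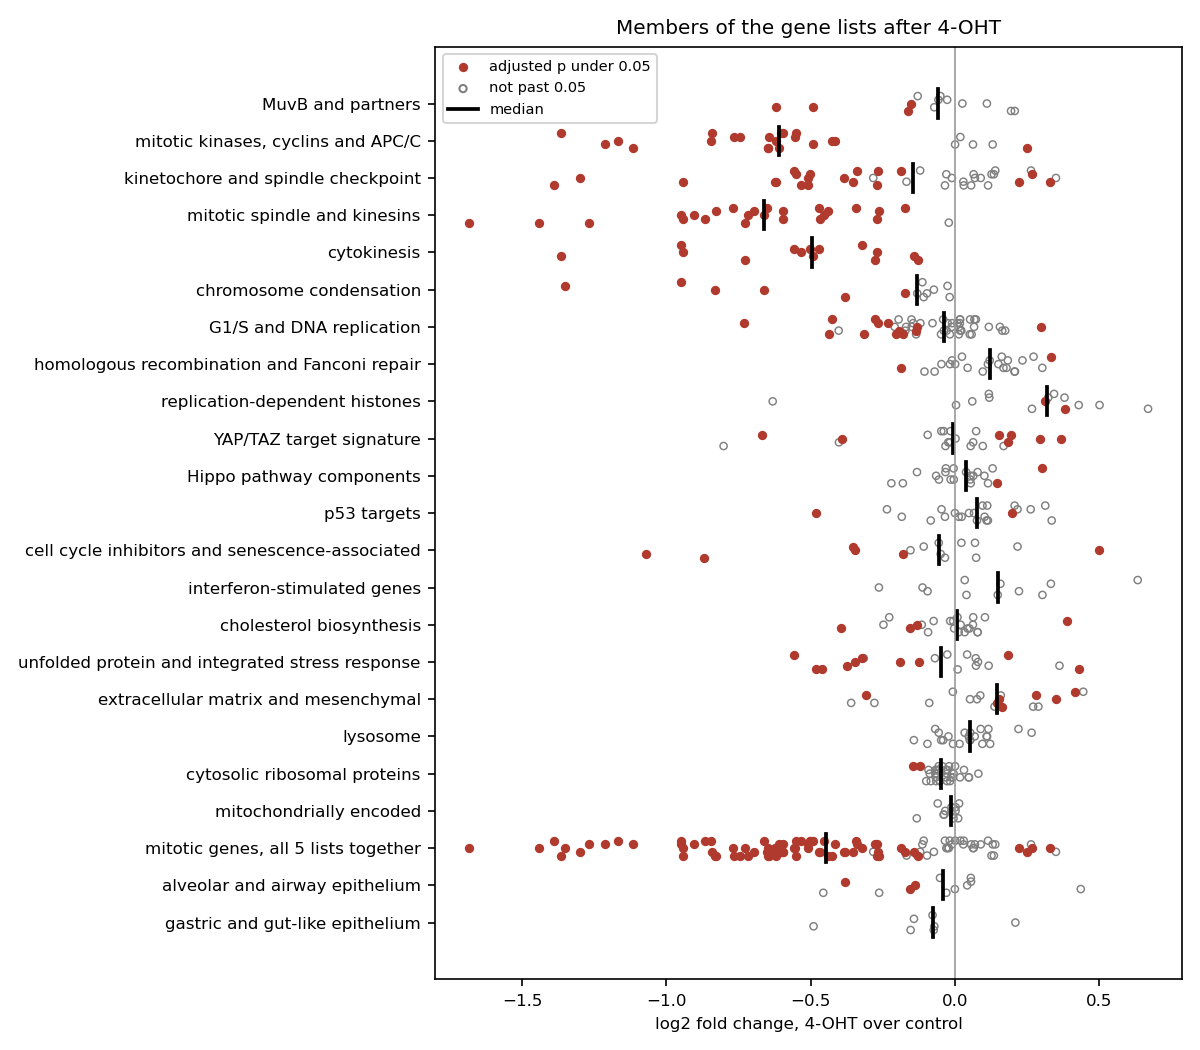
Log2 fold change (4-OHT over control, horizontal axis) of each tested member of every list with at least 3 tested members; filled red points passed an adjusted p of 0.05, open points did not, and the black bar is the median of the list. The medians of the mitotic lists lie between -0.66 and -0.13, and that of the replication list lies at -0.04.

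The G1/S and DNA replication genes, which belong to an earlier part of the cell cycle, were less affected. Of 50 tested genes, 12 were lower, 1 was higher and 37 did not pass (17 lower and 1 higher adjusted over the list alone). The median was -0.04, and the list was lower than the other genes tested (camera adjusted p = 0.00042, and adjusted p = 0.033 with an estimated correlation). E2f8, an E2F-family repressor gene, fell from 44.9 ± 3.95 to 27.03 ± 3.92 CPM (log2 fold change -0.73, SE 0.09), and Uhrf1, which encodes a factor of maintenance DNA methylation, from 167.1 ± 3.45 to 124.2 ± 5.29 CPM (log2 fold change -0.43, SE 0.05). The 1 higher member was Rfc5 (log2 fold change 0.30), a clamp loader subunit gene named after its value was seen; it did not pass in DESeq2 (adjusted p = 0.104). Set against each other, the mitotic genes had a mean log2 fold change of -0.44 and the G1/S genes of -0.09, a difference of -0.35 over 104 and 50 genes (camera p = 5.5e-06, and p = 0.015 with an estimated correlation).

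Within the MuvB list itself, 4 of 13 genes were lower and 0 higher, as when adjusted over the list alone, and the list as a whole did not pass (median -0.06, camera adjusted p = 0.092; adjusted p = 0.361 with an estimated correlation). It passed without 4-OHT replicate 2 (adjusted p = 0.042) and with no low-count filter (adjusted p = 0.048). Besides Lin9, E2f5 fell from 18.7 ± 1.21 to 12.1 ± 0.419 CPM (log2 fold change -0.62, SE 0.13, edgeR adjusted p = 0.00025). Smaller falls were called for E2f4 (log2 fold change -0.16, adjusted p = 0.034) and Foxm1 (-0.15, adjusted p = 0.017). The E2f4 call was lost without any 1 of 5 libraries (adjusted p 0.056 to 0.194) or with library totals alone (0.051), and the Foxm1 call without any 1 of 4 (adjusted p 0.054 to 0.093), and neither passed in DESeq2. Mybl2, which encodes B-MYB, stood at 112.6 ± 3.97 CPM in control and 114.6 ± 1.70 CPM in 4-OHT libraries (log2 fold change 0.03, SE 0.05, adjusted p = 0.847). No call was made for Lin37 (log2 fold change -0.06), Lin52 (-0.05), Lin54 (0.19), Rbbp4 (-0.03), Rbl1 (-0.13), Rbl2 (0.21), Tfdp1 (-0.07) or Tfdp2 (0.11).

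**Figure D3:**
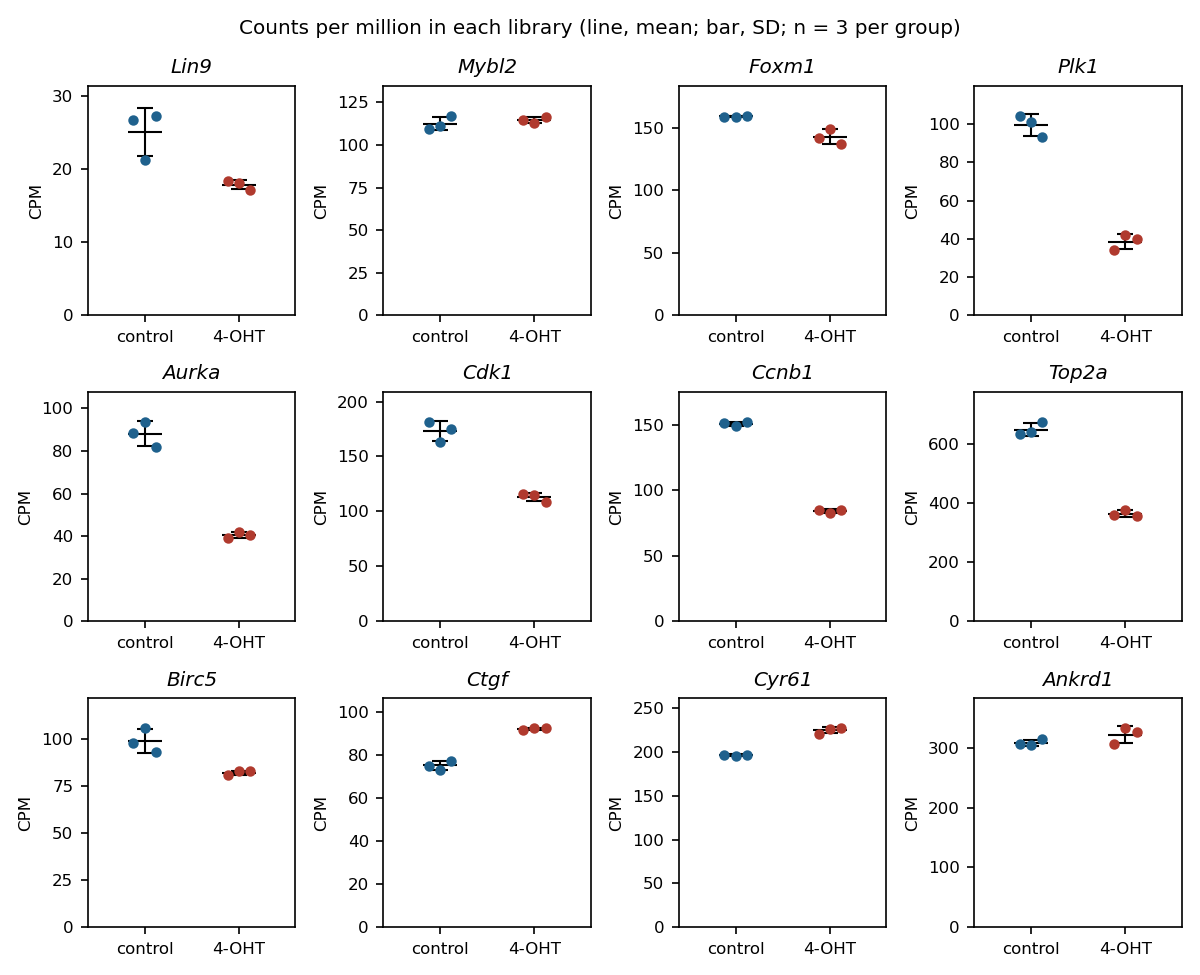
CPM of 12 genes in each of the 3 control and 3 4-OHT libraries (vertical axes from 0, each on its own scale); points are libraries, the horizontal line is the mean and the bar the SD. The 4-OHT libraries lie below the control libraries for Lin9, Foxm1, Plk1, Aurka, Cdk1, Ccnb1, Top2a and Birc5 and above them for Ctgf and Cyr61.

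The series title links the complex to YAP-dependent transcription, so a signature of YAP/TAZ targets was examined. The signature holds none of the mitotic genes above, and no RNA library is labelled as altered in YAP. It therefore does not test whether YAP-dependent transcription of mitotic genes needs the complex. Of 22 tested signature genes, 5 were higher and 2 were lower, as when adjusted over the list alone, and 9.79% of all genes tested were called. Counting movement either way, the fry adjusted p was 6.3e-06, and it was also under 0.05 for most other lists. The list did not pass camera, which asks for a shift 1 way against the other genes (adjusted p = 0.256, and 0.361 with an estimated correlation). Its median of -0.01 and mean of -0.04 were below 0, whereas the direction of camera and fry was upward, and the median lay above 0 when library totals alone scaled the counts (0.0026), without control replicate 3 (0.047) and without 4-OHT replicate 1, 2 or 3 (0.011 each). Ctgf, a matricellular growth factor gene and a common YAP reporter, rose from 75.3 ± 1.99 to 92.2 ± 0.579 CPM (log2 fold change 0.29, SE 0.06, edgeR adjusted p = 9.0e-05), and Cyr61 from 196.1 ± 1.14 to 224.3 ± 3.60 CPM (log2 fold change 0.19, SE 0.04, edgeR adjusted p = 0.00023). No change was called for Ankrd1 (log2 fold change 0.06, adjusted p = 0.328) or Amotl2 (-0.03, adjusted p = 0.726). The remaining members called were Foxf2 (0.37), Crim1 (0.18) and Asap1 (0.15) above control and Gadd45a (-0.67) and Nt5e (-0.39) below it, named after their values were seen. Each of these 5 calls was lost without at least 1 library, with adjusted p up to 0.121 for Foxf2 without control replicate 3, 0.119 for Gadd45a without 4-OHT replicate 1, 0.108 for Asap1 and 0.081 for Crim1 without 4-OHT replicate 2, and 0.073 for Nt5e without control replicate 1. Among 21 Hippo pathway genes 2 were higher and 0 lower, as when adjusted over the list alone (edgeR; camera adjusted p = 0.256). Wwtr1, which encodes TAZ, rose from 180.8 ± 4.93 to 223.0 ± 2.20 CPM (log2 fold change 0.30, SE 0.04). The other was Ajuba (0.14), whose call was lost without control replicate 1, control replicate 2 or 4-OHT replicate 2 (adjusted p 0.088 to 0.177).

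Of 23 tested homologous recombination and Fanconi repair genes, 1 was higher and 1 was lower, as when adjusted over the list alone. The median was 0.12 and the list was higher than the other genes (camera adjusted p = 0.030; adjusted p = 0.133 with an estimated correlation, and adjusted p = 0.086 without Rad18, its most changed member). Rad18, a ubiquitin ligase gene of post-replication repair, rose from 51.9 ± 2.57 to 65.4 ± 2.43 CPM, and Hells, which encodes a chromatin remodelling helicase, fell from 172.4 ± 1.33 to 151.5 ± 6.22 CPM. Of 14 tested replication-dependent histone genes, 2 were higher and 0 lower, as when adjusted over the list alone (edgeR; median 0.32, camera adjusted p = 0.0062; adjusted p = 0.133 with an estimated correlation, 0.272 with no low-count filter and 0.087 without control replicate 1). These were Hist1h1c (log2 fold change 0.38) and Hist1h2bc (0.31), neither past 0.05 in DESeq2. The Hist1h1c call was lost without control replicate 1 (adjusted p = 0.105), and that of Hist1h2bc without control replicate 3 (0.141) or 4-OHT replicate 2 (0.121). Transcripts of these genes mostly lack a polyA tail and the genes are near-identical copies, so their counts in polyA RNA are uncertain.

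Of 15 tested cell cycle inhibitor and senescence-associated genes, 5 were lower and 1 was higher (6 and 1 adjusted over the list alone; edgeR, median -0.06, camera adjusted p = 0.0072, and adjusted p = 0.133 with an estimated correlation). The inhibitor gene Cdkn2c fell from 19.1 ± 0.806 to 10.4 ± 1.92 CPM, and Lmnb1, which encodes lamin B1, from 154.6 ± 2.56 to 121.6 ± 2.67 CPM. Cdkn2d, another inhibitor gene, changed by -1.07 and the chemokine gene Cxcl1 by 0.50 on the log2 scale, both named after their values were seen. The Cxcl1 call was lost without control replicate 2 (adjusted p = 0.128), 4-OHT replicate 2 (0.095) or 4-OHT replicate 3 (0.064), and in DESeq2. Cdkn1a, the p21 gene, also named after its value was seen, was at 34.0 ± 0.606 CPM in control and 33.2 ± 1.89 CPM in 4-OHT libraries (edgeR adjusted p = 0.887). Among 23 tested p53 targets, 1 was higher and 1 lower, as when adjusted over the list alone (edgeR; median 0.08, camera adjusted p = 0.256). Plk2 changed by 0.20 and Sesn2 by -0.48 on the log2 scale. The Plk2 call was lost without 4-OHT replicate 2 (adjusted p = 0.111) and the Sesn2 call without 4-OHT replicate 3 (0.057), and neither passed in DESeq2.

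In metabolism and stress, the unfolded protein and integrated stress response list had 8 lower and 2 higher of 20 tested genes (9 and 4 adjusted over the list alone; edgeR, median -0.05, camera adjusted p = 0.0068, and adjusted p = 0.093 with an estimated correlation). Asns, which encodes asparagine synthetase, fell from 172.1 ± 5.93 to 125.1 ± 7.07 CPM, and Psat1, a serine synthesis enzyme gene, from 391.6 ± 6.57 to 313.3 ± 19.3 CPM. The members above control were Hspa5 (log2 fold change 0.18), the chaperone gene BiP, and Ddit3 (0.43), the gene of the transcription factor CHOP, both named after their values were seen. The Ddit3 call was lost without any 1 of 4 libraries (adjusted p 0.052 to 0.156) and in DESeq2. Of 23 tested cholesterol genes, 3 were lower and 1 higher (5 and 1 adjusted over the list alone; edgeR, camera adjusted p = 0.594). The median was 0.0084, the mean -0.02 and the direction of camera downward. Dhcr7, which encodes an enzyme of the last step of the pathway, changed by 0.39 on the log2 scale and did not pass in DESeq2 (adjusted p = 0.090). Fdps, a farnesyl diphosphate synthase gene named after its value was seen, changed by -0.15, a call lost without any 1 of 4 libraries (adjusted p 0.090 to 0.195).

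Of 19 tested extracellular matrix and mesenchymal genes, 6 were higher and 1 lower, as when adjusted over the list alone (edgeR; median 0.15, camera adjusted p = 0.0062, and adjusted p = 0.255 with an estimated correlation). Col4a2, a basement membrane collagen gene, rose from 272.6 ± 5.29 to 331.0 ± 17.6 CPM, whereas Thbs1, which encodes thrombospondin 1, fell from 420.7 ± 22.0 to 339.5 ± 9.72 CPM. Of 34 tested cytosolic ribosomal protein genes, 2 were lower and 0 higher (1 and 0 adjusted over the list alone; edgeR, median -0.05, camera adjusted p = 0.0062; adjusted p = 0.361 with an estimated correlation and 0.115 without 4-OHT replicate 1). They were Rpl3 (-0.14) and Rpl18 (-0.12), and the Rpl18 call was lost without any 1 of 4 libraries (adjusted p 0.133 to 0.216). Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain. Interferon-stimulated genes (11 tested, median 0.15, camera adjusted p = 0.284), lysosomal genes (23 tested, 0.05, 0.114) and mitochondrially encoded genes (13 tested, -0.01, 0.286) had 0 members past the threshold in edgeR, also adjusted over each list alone, with 1, 5 and 2 members at an unadjusted p under 0.05. The lysosomal list passed without control replicate 2 (adjusted p = 0.041) or 4-OHT replicate 2 (0.047), and the mitochondrial list without control replicate 2 (0.049) or 4-OHT replicate 1 (0.012). The members with the highest levels were Lamp1 (log2 fold change 0.09, adjusted p = 0.085), mt-Co1 (-0.01, 0.863) and, for the interferon list, Ddx58 (0.22, 0.428). Lamp1 passed when library totals alone scaled the counts (adjusted p = 0.040).

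Of 12 tested alveolar and airway epithelium markers, 3 were lower and 0 higher, as when adjusted over the list alone (edgeR; median -0.04, camera adjusted p = 0.089; adjusted p = 0.361 with an estimated correlation). The list passed with a stricter low-count filter (adjusted p = 0.045), without control replicate 3 (0.031) and without 4-OHT replicate 3 (0.016). Epcam, an epithelial adhesion gene, fell from 223.2 ± 2.66 to 171.2 ± 6.76 CPM, and the water channel gene Aqp5 from 432.8 ± 10.4 to 388.7 ± 18.2 CPM. Cdh1, the E-cadherin gene, changed by -0.14 on the log2 scale and was named after its value was seen. Of 7 gastric and gut-like markers 0 passed, and 0 had an unadjusted p under 0.05 (median -0.08, camera adjusted p = 0.256), with Ctse at -0.07 (edgeR adjusted p = 0.431). Of markers of other cell types, 2 fibroblast, 1 endothelial, 2 leukocyte and 0 erythroid genes were tested and 0 passed in edgeR, also at an unadjusted p under 0.05. Their highest were Col1a1 at 6.74 ± 1.99 and 5.25 ± 0.787 CPM (control and 4-OHT), Tek at 5.71 ± 1.59 and 5.36 ± 0.864 CPM, and Itgam at 2.97 ± 1.11 and 2.54 ± 1.18 CPM.

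By the rule for named genes, the largest falls outside the lists were those of 4 genes. They included Pif1, a DNA helicase gene, from 25.1 ± 1.95 to 5.53 ± 0.535 CPM (log2 fold change -2.18, SE 0.15, edgeR adjusted p = 1.2e-22), and Psrc1, which encodes a spindle-associated protein, from 7.60 ± 1.13 to 2.20 ± 1.04 CPM (log2 fold change -1.78, SE 0.26). The other 2 had few reads. The gene 2610318N02Rik changed by -2.11 (SE 0.43), with 18, 17 and 13 reads in control and 4, 4 and 3 in 4-OHT libraries. The dynein heavy chain gene Dnah17 changed by -1.58 (SE 0.44), with 11, 17 and 11 reads in control and 7, 3 and 3 in 4-OHT libraries. The largest rises by the same rule were also in genes with few reads. Zscan4b, of a family of near-identical genes on chromosome 7, was counted at 5, 4 and 3 reads in control and 12, 15 and 21 reads in 4-OHT libraries (log2 fold change 1.95, SE 0.42, edgeR adjusted p = 0.00050), and its count is uncertain because reads of such copies cannot be assigned securely. Acsl6, a fatty acid CoA ligase gene, changed by 1.41 (SE 0.30), Zfp112 by 1.32, Epm2a by 1.26, Slc37a2 by 1.20 and Gpr112 by 1.18 on the log2 scale. Leaving out 1 library ended the calls of Dnah17 (3 libraries, adjusted p 0.060 to 0.101), Zfp112 (2 libraries, 0.083 to 0.147), Epm2a (1 library, 0.057), Slc37a2 (4 libraries, 0.052 to 0.179) and Gpr112 (4 libraries, 0.073 to 0.242).

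The authors' deposited table of the same comparison gave 681 genes lower and 567 higher at an FDR under 0.05. Of the 1307 genes called here, 1180 were also called in the authors' deposited table, all in the same direction, and 127 were called only here. A further 44 genes tested here, and 24 not tested here, were called only in the authors' deposited table. Among genes called in both, the log2 fold changes differed by at most 0.0033.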

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

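The span correction of the list tests, of the mitotic against G1/S comparison and of Lin9, the 1.5-fold null for Lin9, and every alternative for the overlap with the authors' deposited table were chosen after seeing the data. The mitotic lists joined kept their direction and stayed past the threshold in all 16 alternatives run (median -0.47 to -0.42), as did the difference between mitotic and G1/S genes in all 15 (-0.36 to -0.34). Of 80 called named genes, 0 changed sign in any alternative, 28 lost the call without 1 library, 24 in DESeq2 and 64 at the 1.5-fold null.

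DESeq2 called 350 genes lower and 174 higher, all 524 also called in the authors' deposited table, and its median SE was 0.14 against 0.10 in edgeR. Against the 1.5-fold null, 45 genes were lower, 0 higher (edgeR glmTreat, with 92 lower and 44 higher at an unadjusted p under 0.05) and 45 shared with the authors' deposited table, and Lin9, at -0.49, did not pass, since this null asks for a larger change. With 1 library left out, counts ran from 508 to 643 lower and from 403 to 542 higher, with the fewest of both without control replicate 1, where fewer samples entered the fit. With an estimated correlation 7 lists passed in place of 13. Among lists that lost the call, the estimate ran from -0.038 (homologous recombination) to 0.245 (cytosolic ribosomal proteins), against the preset 0.01. For spindle and kinesins it was -0.012, yet the camera adjusted p was 0.0010 in place of 7.1e-65. A higher correlation is therefore not the whole cause. The settings also differ in degrees of freedom, which follow the number of genes with the preset and the 6 libraries with the estimate. The share of each was not tested. With the replicate block, 665 genes were lower and 579 higher and Lin9 changed by -0.49. Samples with the same number did not deviate together (correlations -0.0097, 0.0096 and -0.026), which does not show whether they were handled in pairs.

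Directions turned, with no call before or after, for 6 genes. With 1 library left out, log2 fold changes ran from -0.668 to 0.080 for Itgam (above 0 without control replicate 1), from -0.188 to 0.030 for Lin37 (0.010 without control replicate 2, highest without 4-OHT replicate 3) and from -0.264 to 0.148 for Lin52 (above 0 without 4-OHT replicate 3). They ran from -0.221 to 0.159 for Tek (highest without control replicate 3, 0.014 without 4-OHT replicate 2) and from -0.065 to 0.012 for Cdkn1a (above 0 without 4-OHT replicate 1). For mt-Co1 they ran from -0.048 to 0.0072 (highest without 4-OHT replicate 2, 0.00073 without control replicate 3 and 0.0019 without 4-OHT replicate 3). The median of the cholesterol list ran from -0.0099 to 0.024 with 1 library left out, and its direction in camera turned without control replicate 2. The cause was not tested. Depth limits the genes with few reads, such as those with the largest rises and, among the largest falls, 2610318N02Rik and Dnah17.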

Other observations

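Besides the span correction of the list tests named above, further tests were chosen only after the result was seen. They were those of the gene families, of fewer G2 and M cells, of 4-OHT itself, of the summed Zscan4 count and of the Lin9 count. The bounds for redistribution of the Zscan4 reads were set after the sum was seen, in place of an adjusted p under 0.05 that the sum did not meet. The Aldh1a and annexin genes, and the Zscan4 genes other than Zscan4b, were named after their values were seen. Aldh1a1, a retinaldehyde dehydrogenase gene, fell from 21.3 ± 1.20 to 9.31 ± 1.01 CPM (log2 fold change -1.19, SE 0.13, edgeR adjusted p = 1.6e-11), and its near-identical neighbour Aldh1a7 changed by -1.42 (SE 0.36), and reads of this pair are assigned with uncertainty. Over its 17 alternatives the Aldh1a1 change lay between -1.27 and -1.12. Aldh1a3 rose from 11.6 ± 0.955 to 21.1 ± 2.22 CPM (log2 fold change 0.86, SE 0.13, edgeR adjusted p = 1.7e-07).

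Of 359 gene families formed by symbol stem with at least 5 tested members, 9 passed in camera and 0 passed with an estimated correlation (adjusted p = 0.998). Among the 9 were the annexins, calcium-dependent membrane-binding proteins, with 5 of 10 members higher and 0 lower (edgeR; median 0.13, camera adjusted p = 0.0034, upward also with RLE factors and with library totals alone). Anxa2 rose from 1178.5 ± 1.17 to 1345.0 ± 26.1 CPM and Anxa5 from 691.0 ± 16.5 to 806.0 ± 11.2 CPM. The Anxa1 call was lost without control replicate 1 (adjusted p = 0.052) or 4-OHT replicate 3 (0.053), and the Anxa11 call without any 1 of 3 libraries (0.170 to 0.220).

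The mitotic genes were lower after 4-OHT, with a median of -0.45. A trend on genomic span is argued against as the whole cause. The median was -0.445 after the trend on gene span was removed, against -0.447 before, and the list still passed (camera adjusted p = 7.4e-76). A trend on transcript length stays open, since transcript length was not used here. Fewer cells in G2 and M, with unchanged levels per cell, remains open, since how specific each member is to a phase was not measured. Of the 104 members, 70 were called lower, and the log2 fold changes differed (SD 0.45). The 4 members called higher (0.22 to 0.33) would go against fewer such cells only if they were specific to G2 and M. None of these 4 passed in DESeq2, and the Cenph call was lost without either of 2 libraries. An effect of 4-OHT itself remains open, with 0 RNA libraries of treated cells that keep Lin9. A direct effect of the lower Lin9 level is the hypothesis the design names, and it cannot be told apart from the open ones.

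The 5 Zscan4 genes on chromosome 7 (10900740 to 11402318) had 4 calls above control, Zscan4b, Zscan4c (log2 fold change 1.17), Zscan4e (1.67) and Zscan4f (0.93), and Zscan4d stood at 0.67 (edgeR adjusted p = 0.325). Leaving out 1 library ended the calls of Zscan4c (3 libraries, adjusted p 0.110 to 0.299), Zscan4f (4 libraries, 0.128 to 0.469) and Zscan4e (4-OHT replicate 3, 0.063). Their summed count was 31 to 43 reads in control and 58 to 134 in 4-OHT libraries, a log2 fold change of 1.23 (SE 0.39, edgeR unadjusted p = 0.025, adjusted p = 0.152). Redistribution of reads among these 5 copies would lower some and leave the sum unchanged. No copy lay below 0 in any alternative run (lowest 0.30, Zscan4d). The sum, which restates these values, lay above 0 by more than 2 SE with all libraries and without each (0.84 to 1.47). Its edgeR unadjusted p was 0.080 without control replicate 2 and 0.075 without control replicate 3. Its edgeR adjusted p passed only without 4-OHT replicate 1 (1.0e-09) or 3 (0.00060). The sum met a bound set after its value was seen and missed the earlier one, so redistribution stays open. Reads from copies outside these 5 were not tested, extra copies of the region stay open, since only 3 neighbours within 1 Mb were tested (median 0.071, SE 0.13), and no biological explanation was tested.

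The Lin9 count kept 71.1% of its control level. Reads from exons outside the deleted part, and cells that kept Lin9, cannot be told apart, because both leave 71.1% in a whole-gene count and counts per exon were not used here.

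The 6 libraries form 10 splits of 3 against 3, too few for a share under 0.05. In the 9 splits other than the real one, each group holds both treated and control libraries. The treatment difference thus enters both their contrast and their spread. They are therefore not splits without an effect, and no conclusion is drawn from the comparison with them. In 1 of 10 splits, the real one, as many genes were lower (691) or higher (616), and the highest of the other 9 was 0 in edgeR, with 333 to 546 genes at an unadjusted p under 0.05 and 0 in limma-voom. For the gene lists 1 split of 10 gave as many as 13, and the highest other gave 9 (7 and 0 with an estimated correlation). For the mitotic against G1/S difference 1 split of 10 gave a size as large as 0.35, and the highest other gave 0.13.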
